A study of Mustela putorius furo with 6 samples.

How the data were processed

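The material was brain tissue of wild-type ferrets (Mustela putorius furo), a carnivore whose cortex folds largely after birth. Per the labels, 3 libraries came from the lateral gyrus and 3 from the lateral sulcus. The series text gives postnatal day 4 and the germinal zone, the layers where cortical neurons are born. Per the labels' protocols, RNA was extracted with a column kit for small samples, and 1 ug of total RNA entered a TIANSeq Fast RNA library kit.

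The deposited values are read counts per gene, with 1 file per library and no header or summary lines. They were taken as raw counts because they are whole numbers whose totals differ between libraries. Per the submitters' processing notes, Trimmomatic 0.33, HISAT2, HTSeq 0.6.0, Cufflinks 2.2.1 and Cuffnorm were used, with no order or role stated. The genome build, the annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Counts of overlapping genes, antisense genes and near-identical gene copies are therefore uncertain.

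Each file lists the same 32057 Ensembl ferret gene identifiers and does not pair them with symbols. The gene table used here, of assembly ASM1176430v1.1, gives no Ensembl identifiers and so matched 0 of them. The 37 gene lists of cell types and pathways, the main test, its alternatives and the rule for naming genes were fixed before the data were examined. The lists need symbols and were not tested. No position, gene length or GC content was used.

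Genes were kept with edgeR's filterByExpr at its minimum count of 10, which left 14391 genes holding at least 99.852% of the counts of every library. Libraries were scaled with TMM. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) of the lateral gyrus against the lateral sulcus, 2-sided, over all 6 libraries and without a covariate. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The standard error of a log2 fold change was taken from the fold change and its F statistic. Levels are given as CPM, counts relative to the TMM-scaled library size, and log2 CPM with a prior count of 2 was used for correlations and principal components.

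The labels number the libraries 1 to 3 in both regions, and the series text calls gyrus and sulcus paired without saying that a number marks an animal. Whether the numbers pair the libraries was checked before the calls of the fits were compared. Deviations from the group means correlated across genes at 0.185, 0.554 and 0.643 between the same-numbered libraries 1, 2 and 3. Between libraries with different numbers the values ran from -0.609 to 0.279. The highest of these, for gyrus 2 with sulcus 1, lay above the 0.185 of sulcus 1 with its own partner, so the pairing of number 1 is the least certain. All 3 same-numbered values were over 0.1, the limit used, and the numbers were taken to pair the libraries. The value of gyrus 2 with sulcus 1 passed this limit too, so the limit alone does not single out the pairing. The fit with the replicate number as a block, called the paired fit, called 5 genes where the test without it called 0, and its values stand beside the main ones. Nothing in the labels says that libraries of 1 region came from separate animals. P-values then measure only the spread between these libraries, which may be technical.

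The rule for naming genes asked for a symbol, so no gene met it as written. After the values had been seen, its first part was applied to identifiers in the paired fit. It took genes past the threshold whose groups did not overlap and whose mean in the higher group was at or above the median level of 28.2 CPM. The genes were ranked by fold change. The rule allowed more per direction, but only 2 per direction are given by identifier. The remaining gene of the 5 that passed is described without one.

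Totals ranged from 10931832 to 12344534 counts. The median tested gene had a mean of 321 counts, at which counting error alone gives a coefficient of variation of 5.58%. Taking 3 counts as the limit, a count of 0 allows a level of up to 0.274 CPM in the library with the lowest total. No molecular identifiers are named in the sources used here, so such limits cover counting error only. A chi-square comparison of counts gave at least 6.41 per degree of freedom for every pair of libraries, so none was a near copy of another.

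The fits were tested on simulated counts made from the gene means, replicate effects and dispersions of these libraries. Each of 5 simulations of the comparison of gyrus with sulcus changed 200 of 14391 genes. The test without a block called 0% of the genes changed 1.5-fold, 18.5% of those changed 2-fold and 72.1% of those changed 4-fold. The fit with the replicate block called 47.5%, 76.1% and 93.9%. It also called 51 unchanged genes beside 724 changed ones, 6.58% of its calls, slightly over the 5% that the threshold aims at. edgeR's test without a block called 0 unchanged genes. DESeq2 without a block called 7.46% of the genes changed 1.5-fold, 53.7% of those changed 2-fold and 84.55% of those changed 4-fold. It called 1 unchanged gene beside 484 changed ones. Simulated genes varied independently, so these shares leave out differences that many genes share within 1 pair. The simulated counts also took the replicate effects as real. The gain from the block is therefore built in and is no evidence that the numbers pair the libraries.

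The alternatives were the replicate block, no filter beyond a count in 1 library, a filter of 5 CPM in 3 libraries, DESeq2 size factors in edgeR, library size alone, DESeq2 1.42.0, an added 2-fold minimum, and leaving out each library in turn. The same changes to the paired fit, limma voom with the block (limma 3.58.1), and leaving out both libraries of a number were added after the data were seen.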

Results

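Gene expression was measured by RNA sequencing in the germinal zone beneath neighbouring parts of the ferret cortex, the lateral gyrus, an outward fold, and the lateral sulcus, a groove. The tissue was wild type and taken at postnatal day 4. Each region had 3 libraries, numbered 1 to 3. Lateral gyrus libraries held 11562776 ± 718325 counts and lateral sulcus libraries 11192353 ± 191403 counts (SD, n = 3 each). Of 32057 listed genes, 22015 had a count in at least 1 library and 15598 in all 6. Lateral gyrus libraries detected 18339.7 ± 130.5 genes and lateral sulcus libraries 18186 ± 123 genes (SD, n = 3 each).

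Lateral gyrus and lateral sulcus libraries with the same number resembled each other on average more than libraries of the same region did, with overlapping ranges. Across 14391 tested genes, log2 CPM (counts relative to library size) correlated at 0.975 to 0.983 (mean 0.979) between same-numbered gyrus and sulcus libraries. Libraries of the same region correlated at 0.943 to 0.978 (mean 0.963). The replicate number held 63.7% of the variance, where unstructured variance would give it 40%, and the region held 15.2%, where it would give 20%. Component 1, with 52.1% of the variance, set both libraries numbered 3 apart, at 28.9 for the gyrus and 58.55 for the sulcus, while the other 4 lay between -41.7 and -2.72. On component 2, with 15.6% of the variance, the gyrus library lay above the sulcus library in 3 of 3 pairs. Lateral sulcus replicate 3 stood furthest out, and its 10 most abundant genes took 3.70% of its counts, against 2.58% to 3.12% in the other 5 libraries. No test was run on these values.

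**Figure D1:**
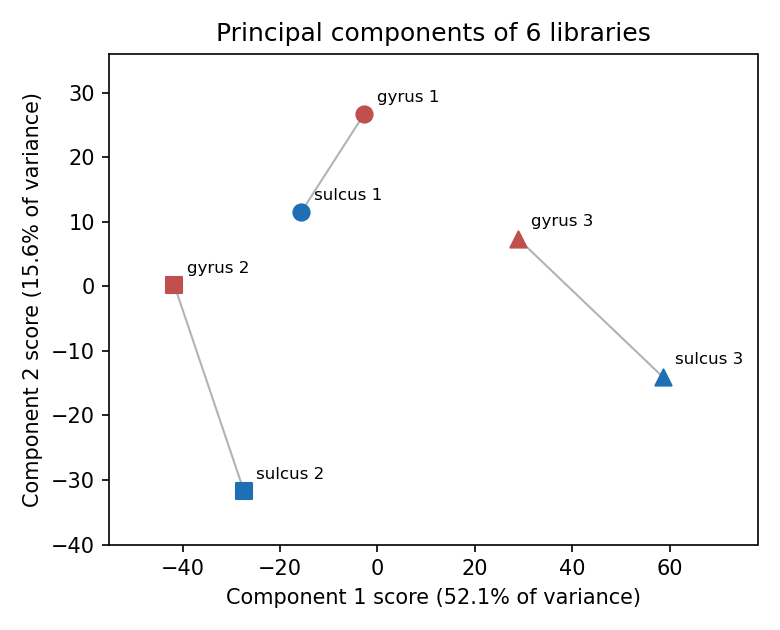
Scores of the 6 libraries on principal component 1 (x axis, 52.1% of the variance) and component 2 (y axis, 15.6%), from log2 CPM of 14391 genes; colours mark the region, marker shapes the replicate number, and grey lines join libraries with the same number. Both libraries numbered 3 lie at positive scores on component 1, and each gyrus library lies above its sulcus partner on component 2.

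The central comparison asked which genes differ between the germinal zones of the lateral gyrus and the lateral sulcus. The main test, without the pairing, called 0 genes, with a lowest edgeR adjusted p of 0.0908. With same-numbered libraries compared as pairs, an alternative to the main test, 5 genes differed, 2 higher and 3 lower in the gyrus. By the fold changes fitted over all 6 libraries without the pairing, ENSMPUG00000012141 was 7.80-fold and ENSMPUG00000013162 2.32-fold higher in the gyrus, while ENSMPUG00000000837 and ENSMPUG00000001730 were each 1.85-fold higher in the sulcus. In the main test, 424 genes had an unadjusted p under 0.05, fewer than the about 719.55 for exchangeable libraries. The files do not pair the identifiers with symbols, so what the 5 genes encode is not reported.

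ENSMPUG00000012141 measured 32.6 ± 5.17 CPM in the gyrus and 4.17 ± 3.83 CPM in the sulcus (SD, n = 3 each). Gyrus replicates 1 to 3 held 453, 403 and 292 counts, and sulcus replicates 23, 97 and 20. The paired log2 fold change was 3.16 ± 0.366 (SE), with an edgeR adjusted p of 0.0358. The log2 ratio was 4.05 in pair 1, 2.01 in pair 2 and 3.70 in pair 3. Without the pairing the log2 fold change was 2.96 ± 0.55 (SE, edgeR adjusted p = 0.665). With the pairing, the call was lost with the stricter filter (edgeR adjusted p = 0.0755) and with limma voom (adjusted p = 0.074). Leaving out lateral sulcus replicate 2 moved the unpaired value to 4.05, with an edgeR adjusted p of 0.0171, and over 12 alternatives to the unpaired test the adjusted p ran from 2.24e-05 to 1.

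ENSMPUG00000013162 varied less between libraries, at 130 ± 5.87 CPM in the gyrus and 56.0 ± 4.81 CPM in the sulcus (SD, n = 3 each). Gyrus replicates held 1543, 1540 and 1450 counts, and sulcus replicates 690, 577 and 595. Its paired log2 fold change was 1.22 ± 0.104 (SE, edgeR adjusted p = 0.014), and the log2 ratios of pairs 1, 2 and 3 were 1.02, 1.39 and 1.24. Without the pairing it was 1.21 ± 0.115 (SE), with an edgeR adjusted p of 0.0908, the lowest of all tested genes. Over 12 alternatives to the unpaired test the adjusted p ran from 2.79e-13 to 0.85.

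The 3 genes that were lower in the gyrus were abundant and differed by similar amounts. Each was lower in the gyrus in 3 of 3 pairs, which follows from the lack of overlap that the naming rule asked for. ENSMPUG00000000837 measured 92.2 ± 10.3 CPM in the gyrus and 170.4 ± 18.6 CPM in the sulcus (SD, n = 3 each). Its paired log2 fold change was -0.89 ± 0.0988 (SE, edgeR adjusted p = 0.0324). ENSMPUG00000001730 measured 123 ± 9.3 CPM in the gyrus and 228 ± 25.3 CPM in the sulcus (SD, n = 3 each). Its paired log2 fold change was -0.88 ± 0.0915 (SE, edgeR adjusted p = 0.0288). The remaining gene measured 103 ± 7.56 CPM in the gyrus and 185 ± 27 CPM in the sulcus (SD, n = 3 each), with a paired log2 fold change of -0.84 ± 0.0889 (SE, edgeR adjusted p = 0.0288). Without the pairing, the log2 fold changes of ENSMPUG00000000837, ENSMPUG00000001730 and the remaining gene were -0.89, -0.89 and -0.85, each with an edgeR adjusted p of 0.644. In the paired fit, the call of ENSMPUG00000000837 was lost with the stricter filter (edgeR adjusted p = 0.0505), and those of ENSMPUG00000001730 (edgeR adjusted p = 0.0631) and the remaining gene without pair 2. Over 12 alternatives to the unpaired test the adjusted p ran from 9.22e-05 to 1 for ENSMPUG00000000837 and from 1.17e-05 to 1 for ENSMPUG00000001730.

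**Figure D2:**
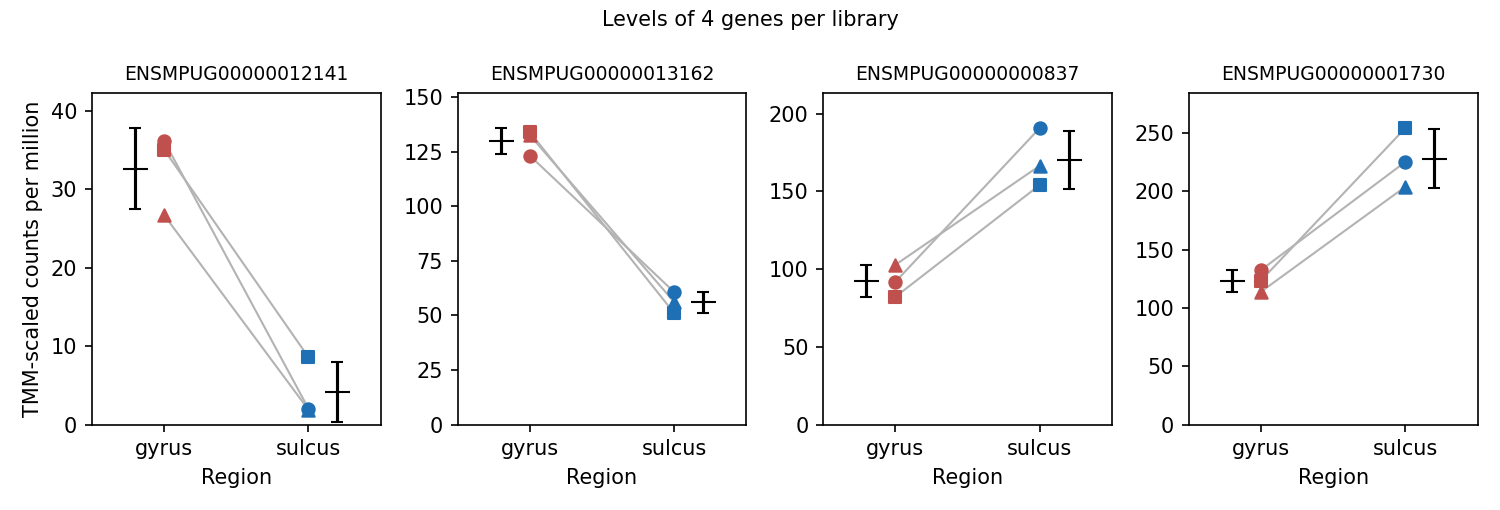
TMM-scaled CPM (y axes, linear from 0, 1 scale per gene) of 4 genes in the lateral gyrus and the lateral sulcus; each point is a library, marker shapes give the replicate number, grey lines join same-numbered libraries, and black bars give the mean ± SD of 3 libraries. ENSMPUG00000012141 and ENSMPUG00000013162 lie higher in every gyrus library than in any sulcus library, and ENSMPUG00000000837 and ENSMPUG00000001730 lie lower. The rule for naming genes required this lack of overlap.

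Most genes had similar levels in the lateral gyrus and the lateral sulcus, with a median absolute log2 fold change of 0.13. An estimated change of at least 2-fold was seen in 248 genes, 1.72% of those tested, 128 higher and 120 lower in the gyrus. Only 8 of the 248 had a mean level at or above that of the median gene. At least 4-fold estimates were seen in 10 genes higher and 1 gene lower in the gyrus. The count of genes with 10 or more counts in every library of 1 region and 0 in every library of the other was 0 in both directions.

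Without the pairing, the lowest adjusted p of edgeR's quasi-likelihood test was 0.0908. Of the 424 genes at an unadjusted p under 0.05, 262 were higher and 162 lower in the gyrus, against about 719.55 if the 6 libraries were exchangeable. The other 9 splits of the libraries gave 52 to 2558 genes. The 3 of them that part all pairs gave 52, 86 and 166, but they mix the regions within each group, where a regional difference adds to the spread and lowers the count. Gyrus and sulcus values did not overlap in 1140 genes, 7.92% of those tested, where chance gives 10% for exchangeable libraries. DESeq2 on the same libraries called 24 genes, 11 higher and 13 lower in the gyrus. Leaving out lateral gyrus replicate 2 lowered the 424 genes to 238, and leaving out lateral sulcus replicate 2 raised edgeR's calls from 0 to 2.

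With the pairing, the biological coefficient of variation was 13.4%, against 25% without it. In edgeR 1264 genes had an unadjusted p under 0.05, 723 higher and 541 lower in the gyrus, against about 719.55 without any regional difference. Exchanging the regions of pair 1 gave 1282 genes, and exchanging those of pair 2 or 3 gave 134 and 304. The count therefore does not single out the real labels of pair 1. Each of the 5 called genes was also called by DESeq2, with and without the pairing, while limma voom called 4 of them and edgeR with the stricter filter 3. DESeq2 with the pairing called 86 genes, 50 higher and 36 lower in the gyrus. Library size alone as the scaling gave 24 genes, 18 higher and 6 lower, which included the 5. Leaving out pair 1, 2 or 3 gave 575, 12 and 127 genes, which included 5, 3 and 5 of the 5, and dropping the low-count filter gave 276. Without a pair, 2 libraries per region remain. edgeR's prior degrees of freedom, the weight given to variance pooled over genes, were then 18.4, 15.8 and 15.1, against 6.95 with all pairs. These counts therefore lean more on pooled variance than the 5 do.

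The difference between gyrus and sulcus was then compared across the 3 pairs, which share no library. Log2 gyrus-to-sulcus ratios of pairs 2 and 3 correlated across genes with a Pearson's r of 0.27 and a Spearman's rho of 0.30. Ratios of pairs 1 and 2 gave 0.073 and 0.062, and those of pairs 1 and 3 gave 0.01 and -0.052. In the third of genes with the highest levels, r was 0.50 for pairs 2 and 3, 0.21 for pairs 1 and 2 and -0.13 for pairs 1 and 3. The ratio had the same sign in all 3 pairs in 4315 genes, 30% of those tested, against 25% for independent signs. Exchanging the regions of pair 1, 2 or 3 gave 30.9%, 16.9% and 22.2%. A gene has 1 sign throughout in only 1 of the real and exchanged arrangements, so a high share in 1 lowers the others. These shares restate how often the signs of 2 pairs agree and are no separate result. The 3 comparisons of pairs run across genes, which are not independent replicates, and no p-value is attached.

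Genes that edgeR called between gyrus and sulcus without 1 of the pairs were followed into that pair. Of 575 genes called from pairs 2 and 3, 314 (54.6%) had the same direction in pair 1, not far from an even split. Of 12 genes called from pairs 1 and 3, 11 (91.7%) had the same direction in pair 2. Of 127 genes called from pairs 1 and 2, 110 (86.6%) had the same direction in pair 3. The differences between these shares were not tested.

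**Figure D3:**
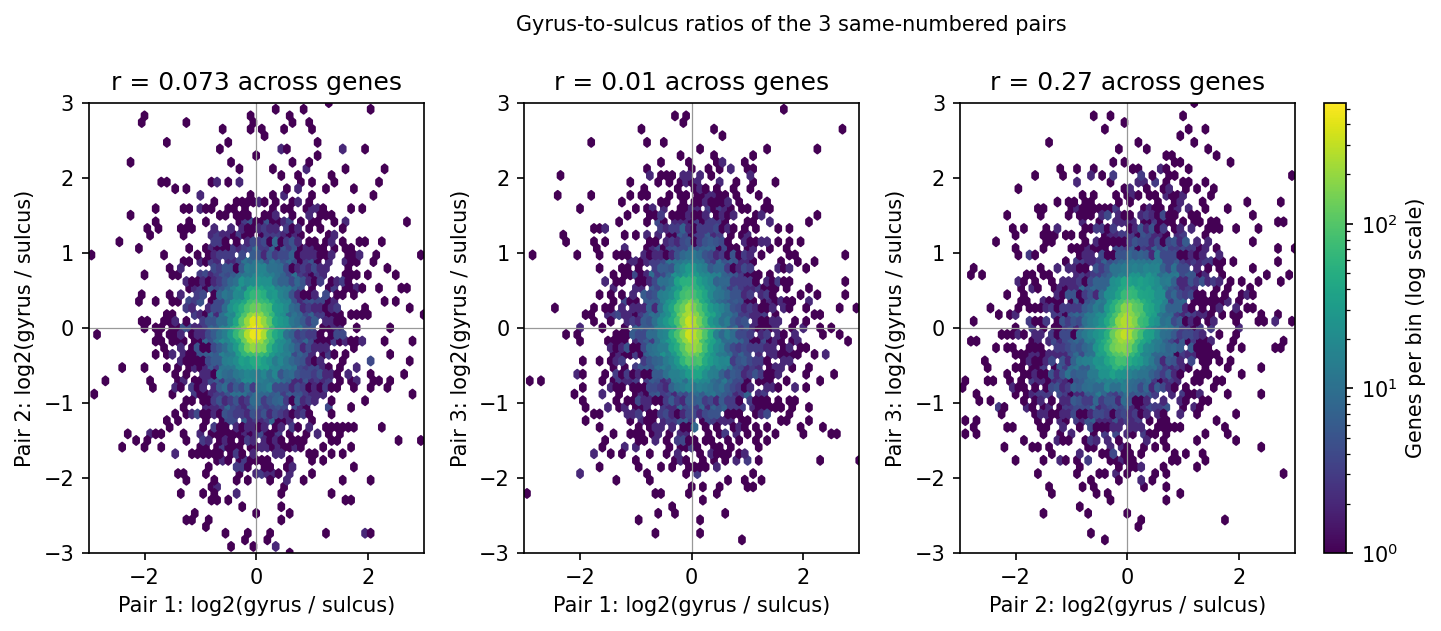
Log2 gyrus-to-sulcus ratios of 14391 genes, with 1 same-numbered pair on the x axis and another on the y axis of each panel, and colour for the number of genes per bin on a log scale; 24 genes lie outside the axes. The correlation across genes is 0.073 for pairs 1 and 2, 0.01 for pairs 1 and 3, and 0.27 for pairs 2 and 3.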

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

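All tests of the paired fit with another setting were chosen after its result was seen; those of the unpaired test were planned. The unpaired count of 0 (424 genes at an unadjusted p under 0.05) became 5 with the replicate block, 24 with DESeq2 and 1 without a filter, and stayed 0 with the stricter filter, DESeq2 size factors in edgeR, library size alone and a 2-fold minimum. Leaving out single libraries gave 0 to 2, the 2 without lateral sulcus replicate 2. The 424 genes became 1264 with the replicate block and ranged from 238 (without lateral gyrus replicate 2) to 618 (without lateral sulcus replicate 3). The 5 genes of the paired fit became 276 without a filter, 3 with the stricter filter, 24 by library size alone, 86 with DESeq2 and 2 with a 2-fold minimum, and 12 to 575 without both libraries of a number. DESeq2 size factors in edgeR kept all 5, and limma voom called 4, all among the 5. All 5 were kept without a filter, by library size alone, by DESeq2 and without replicate 1 or 3, and 3 were kept with the stricter filter and 3 without replicate 2. Without a filter edgeR's prior degrees of freedom were 47 in place of 6.95, exchanging the regions of pair 1 gave 320 calls, and limma voom still called 4. The cause was not tested for any of these changes. In the unpaired test the 4 genes given by identifier kept their direction under all 12 alternatives. Their gyrus and sulcus values do not overlap, as the naming rule asked, so leaving out a library could not reverse them. At the median gene, counting error was 5.58%. The biological coefficient of variation, 1 value for all tested genes, was 25% without the pairing and 13.4% with it. Depth therefore limits mainly the genes far below the median level. The gene list tests were not run, for want of symbols, and the pseudocount alternative applies only to normalized values.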

Other observations

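The tests in this part were chosen after the results had been seen. The counts of the real split, and of the paired fit with the filter over all pairs, are restated from planned tests. Genes at least 2-fold above, or at least 2-fold below, all 4 other libraries in both libraries of a pair numbered 12 for the gyrus and sulcus libraries numbered 1, 63 for those numbered 2 and 109 for those numbered 3. The other 12 combinations of 2 libraries gave 0 to 8. A candidate explanation is that same-numbered libraries share an animal or litter, for which the lowest same-numbered value was 12 and the highest other 8. A shared dissection or library batch cannot be told apart from it, because the number is the only label both would leave.

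Ratios of gyrus to sulcus were more alike in pairs 2 and 3 (r = 0.27 across genes, 0.24 to 0.30 over 200 resamples of genes) than in either with pair 1. Genes are not independent replicates, so the ranges given here leave out the spread between libraries or animals. Removing the 2 axes that separate the pair means lowered r of pairs 2 and 3 to 0.24 (0.20 to 0.26), raised r of pairs 1 and 2 from 0.073 to 0.11 and raised r of pairs 1 and 3 from 0.01 to 0.11 (0.079 to 0.14). The gap between pairs 2 and 3 and pairs 1 and 3 went from 0.26 to 0.13. The axes come from the same libraries as the ratios, so an outlying library enters both. They held 5.4%, 2.66% and 14.4% of the ratio variance of pairs 1, 2 and 3. The change in the gap therefore cannot show whether tissue makeup that also separates the numbers plays a part. That explanation stays open, as does a true difference between animals, which was not tested. Against exchanged gyrus and sulcus labels in pair 1, 54.6% of the genes called from pairs 2 and 3 had the same direction in pair 1, calls from pairs 1 and 2 (127 genes) and from pairs 1 and 3 (12 genes) kept their direction in the remaining pair at 86.6% and 91.7%, and both of these fits called 0 genes after the exchange. Over all pairs, the exchange lowered the calls of the paired fit from 5 to 0 with the filter and raised them from 276 to 320 without it. It gave 1282 genes at an unadjusted p under 0.05 in place of 1264. These counts go both ways, so the exchange is not excluded. Genes with 1 sign in all pairs went from 30% to 30.9%, which restates how signs agree between pairs and is no separate ground.

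Other groupings of the libraries were too few to give a share under 0.05. Without pairing, edgeR called 0 genes in all 10 splits of the 6 libraries, the real one included, so the highest other was also 0. At an unadjusted p under 0.05 the real split had 424 genes, 6 of the 10 splits had at least as many, and the highest other had 2558. That split put lateral gyrus replicate 1 with both libraries numbered 3 and parted only 1 pair, so the samples hold a structure other than the region. The 6 splits that part 1 pair gave 217 to 2558 genes, 5 of them more than the real split and 1, with lateral gyrus replicates 1 and 3 and lateral sulcus replicate 1, fewer. The other 3 splits that part all pairs mix the regions and gave 52, 86 and 166 genes. In the paired fit, 1 of the 4 arrangements within pairs, the real one, had 5 calls, and the highest other had 0. Without a filter, 2 of the 4 had at least the real 276 calls, and the highest other, with pair 1 exchanged, had 320.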
